A study of Mus musculus with 28 samples.

How the data were processed

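RNA was measured in single cells of mouse olfactory tissue with 10x droplet libraries. Of the 28 samples of the series, the 4 single-cell libraries were analysed: WT_OSN (genotype ompgfp, mature olfactory sensory neurons), Rad21cKO_OSN (ompcre;rad21fl/fl;TdTom, mature neurons with a conditional Rad21 deletion), WaplcKO_OSN (Waplflfl;tdTomatoflfl;Omp_cre, olfactory epithelium) and WT_total_OE (wild-type olfactory epithelium). The other 24 samples, which include bulk RNA and chromosome conformation libraries and neurons that overexpress Wapl, were not analysed here. Tissue was dissociated with papain, and neurons were sorted as live cells by DAPI exclusion, per the labels' protocols. Whether the kit read the 3' or the 5' end of transcripts is not given in the sources used here.

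The deposited values were raw UMI counts per gene and barcode, made with Cell Ranger on the mm10 genome per the submitters' processing notes, and the matrices held every barcode, not only cells. Cell Ranger 6.0.1 was stated for WT_total_OE per the submitters' processing notes, and its version for the other 3 libraries is not given in the sources used here. Of the 32285 gene IDs in the files, 32158 matched the GENCODE M21 annotation (GRCm38, the same assembly as mm10), from which all coordinates were taken. 2 different gene IDs carry the name Pcdha11 and were kept apart.

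Cells were called from the counts in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0 and igraph 0.11.9. A barcode was kept if its UMI total reached 10% of the 99th percentile of the top 3000 barcodes and at least 500 UMIs, if it had at least 250 genes, and if at most 10% of its UMIs came from mitochondrially encoded genes. The resulting UMI minimums were 3098 in WT_OSN, 4291 in WT_total_OE, 5375 in Rad21cKO_OSN and 3530 in WaplcKO_OSN. Mitochondrial share removed 7, 24, 9 and 16 barcodes in the same order. The automatic threshold of scrublet marked 0% of cells in each library, so the cells with the highest scores were removed at 0.8% per 1000 cells, which took out 306, 168, 158 and 177. This left 5877, 4410, 4284 and 4531 cells.

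The cells of the 4 libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 1 and a fixed seed. Olfactory, vomeronasal and trace amine receptor genes, clustered protocadherins, mitochondrial, ribosomal protein, haemoglobin, sex-linked marker and the targeted genes were left out of the variable genes. This gave 27 clusters, which were named from 20 lists of cell type markers. A cluster was left unnamed where its leading genes did not hold more markers of its own class than of another. The reference for leading genes, namely the clusters of another best class, was chosen after an earlier clustering had left the mature clusters of WaplcKO_OSN unnamed. Clusters 10, 14 and 22 were unnamed and held 0.596% of cells in WT_OSN, 6.76% in WT_total_OE, 4.93% in Rad21cKO_OSN and 1.52% in WaplcKO_OSN.

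Comparisons were made within the cells named mature olfactory sensory neuron. UMIs were summed over these cells in each library and expressed as CPM, the count per 1e6 of that sum, with exact Poisson 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals. These intervals cover counting error only. Each group had 1 library, so no test, p-value or standard error was computed, and no difference has a replicate check. Each knockout was set beside both wild-type libraries, which differ in genotype and preparation and are not replicates of each other. A ratio to a library at 0 is given as a bound against 3 UMIs in that library, and no ratio is given where both libraries are at or under that floor. Because shares of cells depend on depth, they were computed from all UMIs and again with each cell thinned to 3000 UMIs.

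Genes named singly for each knockout were the 12 with the largest positive and the 12 with the largest negative ratio by the smaller of the 2 log2 ratios, with the same sign and non-overlapping intervals against both wild types. They needed 100 UMIs in the knockout or in both wild-type libraries, and receptor, clustered protocadherin, mitochondrial, ribosomal protein, haemoglobin and sex-linked marker genes were left out. A floor of 3 UMIs in this ranking was adopted after infinite ratios had been seen. Rad21, Wapl and the clustered protocadherins with at least 20 UMIs were always reported. Examples from the gene lists were taken by the same measure. 13 gene lists covered cohesin, odorant transduction, receptor choice, axon guidance, non-clustered protocadherins, activity-dependent genes, dissociation stress, the unfolded protein response, interferon response, p53 response, immature neurons, ribosomal proteins and mitochondrially encoded genes. For a list, the log2 ratios against the 2 wild types were averaged per gene with 0.5 counts added. The median was placed among 10000 random lists of the same size matched on mean expression in 10 bins, over genes with at least 20 UMIs. Of the 20 marker lists, 14 had at least 3 measured members and were scored the same way.

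Free RNA was profiled from barcodes of 1 to 50 UMIs, and its share in mature neurons was estimated from sustentacular markers, which gave more than some other genes allow. A leading receptor needed at least 3 UMIs and more than any other receptor of the cell, and the effective number of receptors is the exponential of the Shannon entropy over leading receptors in equal numbers of cells, averaged over 100 draws. The cell filters, the clustering, the gene lists, the rule for named genes and the comparisons were fixed before the data were examined, except for the reference used in naming clusters, which affects the cells compared, and the floor of 3 UMIs in the ranking of named genes.

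The ratio and list steps were tested on simulated data drawn from the real means and depths of 9244 genes, 200.0 of them changed. All simulated libraries had Poisson error around the pooled wild-type means, without other variation between libraries. Coverage near 95% was therefore built in, and it checks the computation, not how far real libraries differ. The 95% interval held the true ratio for 94, 100, 98 and 98% of genes changed by 2, 4, 0.5 and 0.25-fold in the simulated Rad21cKO_OSN comparison and for 95.0% of unchanged genes. In the simulated WaplcKO_OSN comparison these shares were 96, 98, 98 and 96%, and 94.7%. Intervals lay apart from both wild types, in either direction, for 5.86% and 6.46% of unchanged genes in the 2 simulations. A list of 20 genes raised 2-fold stood at percentile 100 in both, and 7% of 100 unchanged lists fell outside the central 95% of random lists.

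Alternatives tried were a minimum of 1000 UMIs, at most 5% mitochondrial UMIs, doublets kept, TMM factors from edgeR 4.0.16 (R 4.3.3), scaling without receptor, mitochondrial and ribosomal protein genes, each library clustered by itself, neurons with a maturity marker and no Gap43 or Gng8 UMI, free RNA subtracted, each wild type alone, thinned cells, no filter on low counts, and only isoforms with at least 20 UMIs. Splits by Nqo1, single clusters and a stricter rule for named genes were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.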

Results

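Single-cell RNA counts were collected from 4 mouse libraries with 1 library per group: sorted wild-type olfactory sensory neurons (WT_OSN), wild-type whole olfactory epithelium (WT_total_OE), neurons with an Omp-cre deletion of Rad21 (Rad21cKO_OSN) and olfactory tissue with an Omp-cre deletion of Wapl (WaplcKO_OSN). Omp-cre acts in olfactory sensory neurons as they mature. The files held 78873526, 65170018, 64830983 and 68523939 UMIs in that order. Mature olfactory sensory neurons made up 5745 of 5877 cells in WT_OSN (97.8%), 1750.0 of 4410.0 in WT_total_OE (39.7%), 3683 of 4284 in Rad21cKO_OSN (86.0%) and 3435 of 4531 in WaplcKO_OSN (75.8%). Their median depths were 11160.0, 8086.5, 11374 and 12780.0 UMIs per cell, and their summed depths 65118544, 14731537, 43160045 and 44105610.0 UMIs. Most mature neurons of WT_OSN lay in clusters 3, 0, 2 and 4 (1788, 1606, 861 and 787 cells), and those of WT_total_OE in clusters 3, 4 and 0 (602, 378 and 345). Those of Rad21cKO_OSN lay in clusters 21 and 26 (2485 and 829), and those of WaplcKO_OSN in clusters 5, 7 and 1 (1364, 1266 and 632). All comparisons below between genotypes are therefore between mature neurons that fell largely in different clusters. Sex markers also differed: mature neurons of WaplcKO_OSN had Xist at 0 CPM and Ddx3y at 19.0. Xist was at 237 CPM in WT_OSN, 241 in WT_total_OE and 376 in Rad21cKO_OSN, all without a Ddx3y UMI. Comparisons of WaplcKO_OSN with wild type therefore cannot tell loss of Wapl from sex.

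The targeted genes were examined first, because they check the labels. Rad21, the kleisin subunit that closes the cohesin ring (ENSMUSG00000022314, GRCm38 chromosome 15, 51962240 to 51991747), was at 11.0 CPM (10.02 to 12.02) in Rad21cKO_OSN mature neurons, against 165 in WT_OSN, 143 in WT_total_OE and 150 in WaplcKO_OSN. Its log2 ratio was -3.91 (-4.04 to -3.78) against WT_OSN and -3.70 (-3.85 to -3.56) against WT_total_OE, or 15.02-fold and 13.04-fold lower. Wapl, which releases cohesin from DNA (ENSMUSG00000041408, chromosome 14, 34673928 to 34747983), was at 20.9 CPM (19.6 to 22.3) in WaplcKO_OSN, against 77.4 in WT_OSN, 58.6 in WT_total_OE and 88.8 in Rad21cKO_OSN. Its log2 ratio was -1.89 (-1.99 to -1.79) against WT_OSN and -1.49 (-1.62 to -1.35) against WT_total_OE, or 3.70-fold and 2.80-fold lower. In Rad21cKO_OSN, Wapl was higher than in both wild types, by 0.20 and 0.60 on the log2 scale. Outside the mature class of Rad21cKO_OSN, Rad21 stood at 163 CPM in 23 fibroblasts, 117 in 20 sustentacular cells and 86.6 in 152 microvillous cells. It stood at 81.7 in 21 ensheathing glia and 78.7 in 76 macrophages. In WaplcKO_OSN, Wapl stood at 166 CPM in 28 neuronal precursors and in 30 microvillous cells, 68.4 in 430 sustentacular cells and 35.8 in 379 immature neurons. Levels in the smaller of these classes rest on few cells and are rough. With all UMIs, Rad21 was seen in 80.1, 67.9, 8.85 and 82.5% of mature neurons of WT_OSN, WT_total_OE, Rad21cKO_OSN and WaplcKO_OSN, and with thinned cells in 37.9, 33.9, 2.85 and 34.8%. Wapl was seen in 56.5, 37.9, 62.6 and 22.9%, and with thinned cells in 20.9, 16.2, 24.1 and 6.58%. Omp, the marker of mature neurons and the locus that drives cre, was at 5489 CPM in WT_OSN, 4938 in WT_total_OE, 3531 in Rad21cKO_OSN and 4086 in WaplcKO_OSN, with log2 ratios of -0.64 and -0.48 in Rad21cKO_OSN and -0.43 and -0.27 in WaplcKO_OSN. No cell class here lacks Rad21 or Wapl and can serve as background, and a floxed allele can still give UMIs outside its deleted exons.

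Other cohesin genes differed less. Stag1, which encodes an alternative cohesin subunit (chromosome 9, 100597798 to 100959375), was at 28.9 CPM in WT_OSN, 24.6 in WT_total_OE, 50.2 in Rad21cKO_OSN and 12.1 in WaplcKO_OSN. That was 0.80 and 1.03 higher on the log2 scale in Rad21cKO_OSN, and -1.25 and -1.02 in WaplcKO_OSN. Stag2 was 0.42 and 0.57 higher in Rad21cKO_OSN. Ctcf, the insulator protein that halts cohesin, had log2 ratios of 0.16 and 0.25 in Rad21cKO_OSN and -0.33 and -0.24 in WaplcKO_OSN. Pds5b, a cohesin regulator, was 0.46 and 0.89 higher in WaplcKO_OSN. Smc3, a core ring subunit, was at 117, 103, 119 and 119 CPM. As a list, the 13 measured cohesin genes had a median log2 ratio of 0.11 in Rad21cKO_OSN (percentile 69.8 of random lists) and -0.09 in WaplcKO_OSN (percentile 11.0), inside the central 95% in both.

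The question of the series is how cohesin and Wapl set RNA from the clustered protocadherins, cell surface proteins whose alpha, beta and gamma genes lie side by side on chromosome 18 (36930184 to 37841873) and give each neuron an identity code. In Rad21cKO_OSN, alternate alpha isoforms, beta isoforms 2 to 22 and gamma A and B isoforms were all lower than in both wild types, while Pcdhac2 was higher. The 12 alternate alpha genes together were at 20.5 CPM (19.2 to 21.9) against 92.9 and 93.8, 4.53-fold and 4.58-fold lower, with log2 ratios of -2.18 (-2.28 to -2.08) and -2.19 (-2.32 to -2.07). The 21 beta genes (37294812 to 37524479) were at 14.0 CPM (12.9 to 15.2) against 98.7 and 94.6, 7.03-fold and 6.74-fold lower, with log2 ratios of -2.81 (-2.94 to -2.69) and -2.75 (-2.89 to -2.61). The 18 gamma A and B genes were at 12.7 CPM (11.6 to 13.8) against 57.5 and 45.4, with log2 ratios of -2.18 (-2.31 to -2.05) and -1.84 (-2.01 to -1.68). Pcdhac2, the last alpha isoform (37143503 to 37187657), was at 44.2 CPM (42.2 to 46.2) against 11.7 and 11.0, 3.76-fold and 4.02-fold higher, with log2 ratios of 1.91 (1.79 to 2.03) and 2.01 (1.78 to 2.25). It gave 65.2% (63.5 to 67.0) of alpha UMIs, against 10.7% (10.0 to 11.5) in WT_OSN and 10.1% (8.70 to 11.7) in WT_total_OE.

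**Figure D1:**
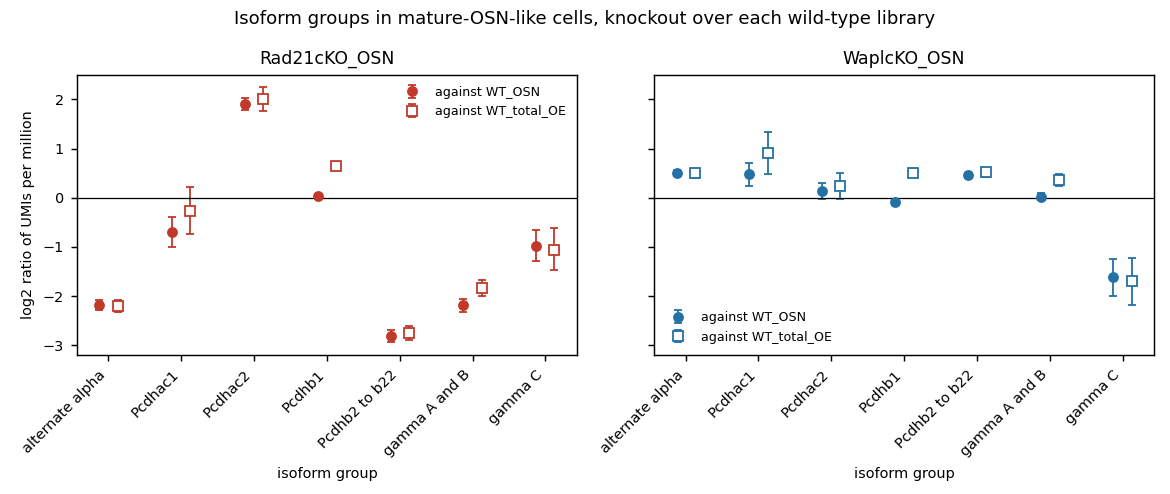
Log2 ratio of CPM in mature neurons (vertical axis) for 7 isoform groups (horizontal axis), Rad21cKO_OSN left and WaplcKO_OSN right, against WT_OSN (filled) and WT_total_OE (open), with 95% counting intervals. In Rad21cKO_OSN the alternate alpha, beta 2 to 22 and gamma A and B groups lie between -2.81 and -1.84 and Pcdhac2 at 1.91 and 2.01; in WaplcKO_OSN alternate alpha and beta 2 to 22 lie between 0.45 and 0.51 and gamma C at -1.62 and -1.69.

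The remaining isoform groups differed in other ways in Rad21cKO_OSN. Pcdhac1 (chromosome 18, 37090013 to 37187657) had log2 ratios of -0.69 (-0.99 to -0.39) against WT_OSN and -0.26 (-0.73 to 0.22) against WT_total_OE, the latter not detectable at this depth. Pcdhb1 (37264938 to 37267525), the isoform with the most UMIs, was at 187 CPM against 182 in WT_OSN and 120 in WT_total_OE, log2 ratios of 0.04 (0.00 to 0.08) and 0.65 (0.57 to 0.72). The 3 gamma C genes (37806364 to 37841873) had log2 ratios of -0.97 (-1.30 to -0.66) and -1.05 (-1.48 to -0.62). All 57 genes together were at 284 CPM against 453 and 374.

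Single isoforms were examined in genomic order. Each of the 12 alternate alpha genes was lower in Rad21cKO_OSN than in both wild types beyond counting intervals, with log2 ratios from -3.26 to -1.26 against WT_OSN and from -2.93 to -1.64 against WT_total_OE. Pcdha12 had -3.26 and -1.69, Pcdha9 -3.21 and -2.79, and Pcdha1 -1.73 and -1.88. Of the 21 beta genes, 21 were lower than both and 18 beyond intervals. Pcdhb21 had log2 ratios of -4.94 and -4.55, Pcdhb12 -4.24 and -4.60, Pcdhb19 -4.17 and -4.07, and Pcdhb20 -3.98 and -3.73. Pcdhb3 was at 0.86 CPM against 0.88 in both, with log2 ratios of -0.03 and -0.04. Of the 18 gamma A and B genes, 17 were lower than both, 16 beyond intervals; Pcdhga4 stood at 3 UMIs in Rad21cKO_OSN and in WT_total_OE, so no ratio is given there. Pcdhgb5 had -4.13 and -4.58, and Pcdhga8 -0.37 and -0.37. Among gamma C genes, Pcdhgc3 had -1.22 and -1.45, while Pcdhgc4 had -0.21 and 1.15. The last exons of alpha and of gamma genes are shared and the end of transcripts that was read is not given in the sources used here, so alpha and gamma values cover only UMIs that counting assigned to 1 isoform. In the 303 Rad21cKO_OSN neurons of cluster 6, the one large cluster shared with WT_OSN, gamma A and B were -2.55 by the smaller ratio instead of -1.84. In 53 Rad21cKO_OSN neurons of clusters 1, 5 and 7, Rad21 was at -2.97 and -2.62, yet alternate alpha was at 0.17 (-0.18 to 0.51) and 0.30 from 82 UMIs.

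**Figure D2:**
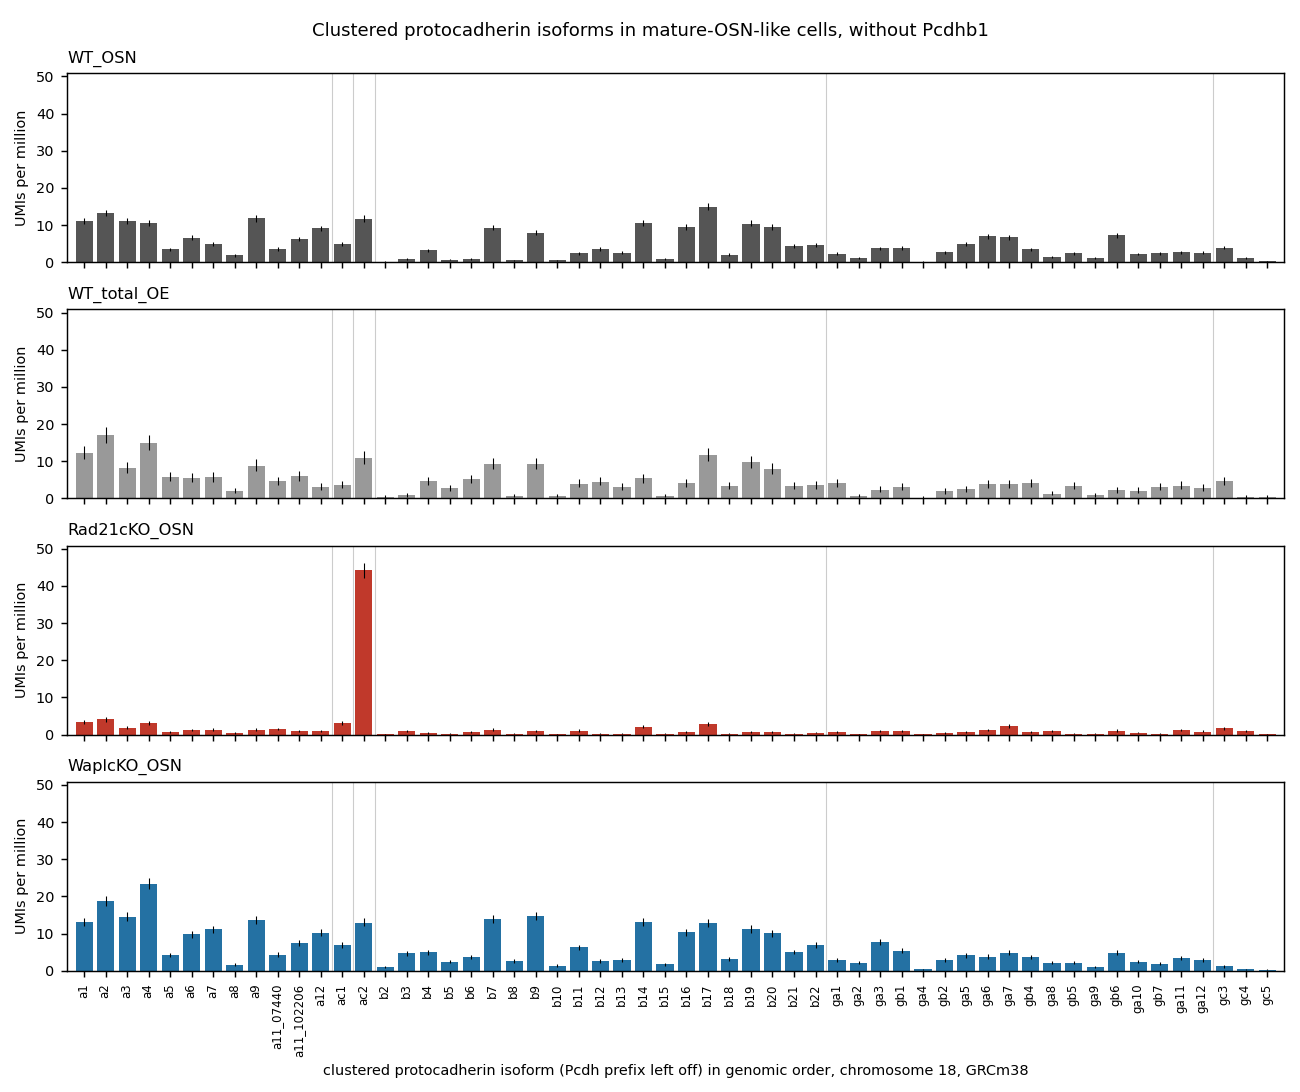
CPM in mature neurons (vertical axis) of each clustered protocadherin isoform but Pcdhb1, in genomic order (horizontal axis), for the 4 libraries; bars are values and lines 95% counting intervals. Pcdhac2 stands at 44.2 in Rad21cKO_OSN, where the alternate alpha genes sum to 20.5 and the beta genes to 14.0.

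In WaplcKO_OSN, alternate alpha and beta isoforms were higher than in both wild types and gamma C isoforms lower, in a class where immature neuron genes were also higher, with a list median of 0.60 (percentile 100). Sex markers also set this library apart from both wild types. Alternate alpha isoforms were at 132 CPM (129 to 136), 1.42-fold and 1.41-fold higher than in WT_OSN and WT_total_OE, with log2 ratios of 0.51 (0.46 to 0.56) and 0.50 (0.41 to 0.58). Beta 2 to 22 isoforms were at 135 CPM (132 to 139), with log2 ratios of 0.45 (0.40 to 0.51) and 0.51 (0.43 to 0.60). Gamma C isoforms were at 1.68 CPM (1.32 to 2.11) against 5.14 and 5.43, 3.07-fold and 3.24-fold lower, with log2 ratios of -1.62 and -1.69 (-2.17 to -1.22 against WT_total_OE). Pcdhac1 had log2 ratios of 0.47 (0.24 to 0.71) and 0.90 (0.48 to 1.35). Pcdhac2 had 0.14 (-0.02 to 0.30) and 0.24 (-0.02 to 0.50), a difference not detectable at this depth, and gave 8.53% of alpha UMIs. Pcdhb1 lay below WT_OSN and above WT_total_OE (-0.10 and 0.51), and gamma A and B had 0.02 (-0.05 to 0.10) and 0.36 (0.24 to 0.49).

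Among single isoforms in WaplcKO_OSN, 9 of 12 alternate alpha genes were higher than in both wild types, 5 of them beyond intervals. Pcdha7 had log2 ratios of 1.22 and 0.98, and Pcdha4 1.14 and 0.64. Of the 21 beta genes, 15 were higher than both, 10 beyond intervals, and 1 was lower. By the smaller ratio, Pcdhb3 was furthest above, at 4.67 CPM (log2 ratios of 2.42 and 2.40), and Pcdhb8 had 2.40 and 1.89, Pcdhb2 2.73 and 1.32, Pcdhb10 1.47 and 1.11, and Pcdhb15 1.07 and 1.36. Pcdhb12 was the lower one, at -0.44 and -0.79. In the gamma cluster, Pcdhga2 had 0.91 and 1.85, Pcdhga3 1.05 and 1.74, and 8 of 18 A and B genes were higher than both, 3 lower. Of the 3 gamma C genes, 3 were lower than both and 1 beyond intervals, Pcdhgc3 at -1.75 and -1.98. In clusters 1, 5 and 7 alone, which hold 3262 WaplcKO_OSN neurons, the smaller ratios of alternate alpha and beta 2 to 22 were 0.23 and 0.22 instead of 0.50 and 0.45, that of Pcdhac2 turned to -0.63 and Pcdhac1 went in opposite directions against the 2 wild types. With each library clustered by itself, Pcdhac2 was at -0.02.

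Per cell, fewer neurons of Rad21cKO_OSN and more of WaplcKO_OSN had clustered protocadherin UMIs. With cells thinned to 3000 UMIs, an isoform other than Pcdhb1 was seen in 53.9% (52.6 to 55.2) of WT_OSN, 51.0% (48.6 to 53.3) of WT_total_OE, 24.2% (22.8 to 25.6) of Rad21cKO_OSN and 62.0% (60.3 to 63.6) of WaplcKO_OSN mature neurons. The mean number of isoforms seen was 0.791, 0.713, 0.275 and 0.966 per thinned cell. Thinned Rad21cKO_OSN neurons had a Pcdhac2 UMI in 12.4% (11.4 to 13.5), against 3.20, 2.97 and 3.58% in WT_OSN, WT_total_OE and WaplcKO_OSN. With all UMIs, Pcdhac2 was seen in 39.5% of Rad21cKO_OSN mature neurons (median depth 11374). It was seen in 2.63% (0.320 to 9.18) of the library's 76 macrophages (median depth 9578.5), a class taken to lack these genes. The leading genes of the cluster named macrophage also included Mpo, Elane and Prtn3, so the class may not hold macrophages alone. Alternate alpha UMIs were seen in 18.8% of Rad21cKO_OSN mature neurons and 1.32% of these macrophages. In WT_total_OE, the matching shares were 50.6% of mature neurons (median depth 8086.5) and 4.30% of 93 macrophages (median depth 10671), and in WaplcKO_OSN 76.8% (median depth 12780.0) and 10% of 20 macrophages (median depth 9744.5).

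Within single neurons, UMIs of a class often came from 1 isoform. When 2 beta UMIs were drawn from a neuron that had them, they were of the same isoform in 47.3% (44.8 to 49.7) of WT_OSN, 35.6% (30.5 to 41.0) of WT_total_OE, 45.2% (35.4 to 55.3) of Rad21cKO_OSN and 28.7% (26.5 to 31.0) of WaplcKO_OSN neurons. A draw from the isoform mix of each library would give 8.79, 7.75, 9.93 and 7.17%. For alternate alpha isoforms the shares were 46.6, 46.3, 59.1 and 45.8%, and for gamma A and B 38.7, 36.0, 46.5 and 29.7%.

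Olfactory receptor genes, of which a mature neuron uses a single allele, were near wild-type levels in both knockouts. The 1135 Olfr genes summed to 12475 CPM in WT_OSN, 10789 in WT_total_OE, 11037 in Rad21cKO_OSN and 9898 in WaplcKO_OSN. The log2 ratios were -0.18 and 0.03 in Rad21cKO_OSN and -0.33 and -0.12 in WaplcKO_OSN. A leading receptor was found in 97.6, 96.5, 93.4 and 92.1% of mature neurons, and a second receptor with 3 or more UMIs in 9.87, 12.6, 9.61 and 7.10%. The effective number of receptors in 1688 cells was 397 in WT_OSN, 606 in WT_total_OE, 425 in Rad21cKO_OSN and 596 in WaplcKO_OSN. The most common leading receptor was Olfr536 in both wild types (1.59 and 0.889% of neurons), Olfr728 in Rad21cKO_OSN (1.43%) and Olfr1507 in WaplcKO_OSN (0.759%). The 15 trace amine receptor genes, used by a dorsal group of neurons, summed to 15.96, 39.4, 8.11 and 84.8 CPM.

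Across all genes, Ptn, Ptprz1, Creb3l1 and Miat were among the genes furthest below both wild types in Rad21cKO_OSN mature neurons. Cpt1a and Lama3 were among those furthest above. Miat and Lama3 were not particular to this library, with -6.09 and 7.31 in WaplcKO_OSN by the smaller ratio. Ptn, a secreted heparin-binding growth factor, was at 11.6 CPM against 350 and 297 (log2 ratios of -4.91 and -4.67), and Ptprz1, a receptor phosphatase that binds it, had 3 UMIs and log2 ratios of -6.62 (-8.91 to -5.07) and -7.62 (-9.91 to -6.06). Creb3l1, a transcription factor anchored in the endoplasmic reticulum, was at 2.09 CPM against 113 and 84.0 (-5.77 and -5.33). The long noncoding RNA Miat (chromosome 5, 112213228 to 112229395) had no UMI, at least 423-fold lower than WT_OSN and 537-fold lower than WT_total_OE. Cpt1a, which brings fatty acids into mitochondria (chromosome 19, 3322334 to 3385733), was at 87.0 CPM against 0.98 and 0.95 (6.47 and 6.52), and Lama3, a laminin chain, at 26.9 CPM against 0.11 and 0.07 (7.97, with 8.63 (6.15 to 13.94) against 1 UMI in WT_total_OE).

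The other genes furthest below both wild types in Rad21cKO_OSN were of several kinds. Stac, an SH3 domain adaptor, had log2 ratios of -5.22 and -5.34, the organic anion transporter family gene Slco5a1 -5.09 and -4.77, and the extracellular matrix gene Sned1 -4.64 and -4.71. Nexn, an actin-binding protein, had 1 UMI and ratios of -7.67 (-12.98 to -5.18) and -8.94 (-14.26 to -6.45). H2-DMb1, part of the class II antigen loading machinery, had -6.35 and -4.80. BC023719 had no UMI and was at least 656-fold and 272-fold lower, and Gm13757 likewise at least 89.3-fold and 229-fold lower. Gm10260 had 3 UMIs against 253 and 326 CPM, log2 ratios of -11.83 (-14.11 to -10.29) and -12.19 (-14.47 to -10.65). Counts of predicted genes such as the last pair can be split with near-identical copies and are uncertain. Nexn, H2-DMb1, BC023719, Gm13757 and Gm10260 were not particular to this library. Each was also at least 4-fold below both wild types in WaplcKO_OSN.

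Of the 12 genes furthest above both wild types in Rad21cKO_OSN, Bpifb9b, Bpifb9a, Gm6999 and Lama3 were also at least 4-fold above both in WaplcKO_OSN. Of these 12, 8 were far more abundant in nearly empty barcodes of Rad21cKO_OSN than in its neurons. Bpifb9b, a secreted protein gene of nasal glands (chromosome 2, 154307227 to 154320646), was at 591 CPM in neurons and 20263 in those barcodes, with log2 ratios of 14.23 (12.38 to 17.28) and 12.09 (10.23 to 15.13) from 2 UMIs in each wild type. Its neighbour Bpifb9a was at 250 CPM in neurons and 9384 in nearly empty barcodes, a ratio of 12.99 (11.14 to 16.04) against 2 UMIs in WT_OSN and at least 1226-fold above WT_total_OE. The odorant-binding protein gene Obp1a was at 202 CPM in neurons and 6138 in those barcodes (12.10 (10.55 to 14.38) against 3 UMIs, and 6.84). The major urinary protein gene Mup4 was at 56.0 CPM (11.83 (9.35 to 17.14) against 1 UMI, and 7.37). Gm14744 was at 135 CPM, at least 2928-fold above WT_OSN and 7.26 above WT_total_OE on the log2 scale, and 5430402E10Rik at 106 CPM, at least 2295-fold and 8.28. Gm6619 and 5430401F13Rik were at 51.0 and 20.1 CPM with no UMI in either wild type, at least 1106-fold and 250-fold higher for Gm6619 and at least 436-fold and 98.5-fold for 5430401F13Rik. Gm6999 (7.66 and 6.95) and 1700018A04Rik (8.41, with 8.26 (5.78 to 13.57) against 1 UMI) had similar levels there, at 59.1 and 16.7 CPM against 58.8 and 20.9 in neurons, as did Cpt1a, at 68.2 against 87.0, while Lama3 was at 13.6 against 26.9.

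Among genes well expressed in both wild types, a rule chosen after the data had been seen gave a different set of genes higher in Rad21cKO_OSN. Prph, the intermediate filament peripherin, was at 202 CPM against 4.70 and 7.60 (log2 ratios of 5.43 and 4.73). Dclk3, a doublecortin-like kinase, was at 639.8 CPM against 89.8 and 90.9 (2.83 and 2.82), and the actin-binding protein drebrin, Dbn1, at 149 against 32.8 and 28.9 (2.19 and 2.37). Marcks, an actin-associated kinase substrate, had 2.45 and 1.85, and the integrin activator Fermt2 2.29 and 1.88. Of the 24 genes named by the ranking across all genes, whose floor of 3 UMIs was itself adopted after the data had been seen, 11 were still named once free RNA was subtracted, at a share estimated from sustentacular markers that is too high for Bpifb9b. With 100 UMIs required in both wild types, 12 of the 24 were.

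Gene lists in Rad21cKO_OSN differed from random lists for 5 of 13. Immature neuron genes were lower, with a median log2 ratio of -0.41 (percentile 0.05) and 10 of 16 lower than both wild types; Gap43, a growth cone protein, had -3.14 and -3.85 and Stmn1 -0.50 and -1.74, while Tubb3 had 1.49 and 1.06. Ribosomal protein genes had a median of -0.37 (percentile 0), 79 of 96 lower than both, with Rplp1 at -0.64 and -0.98; Rps18 was the other way at 2.18 and 2.45. Mitochondrially encoded genes were higher, with a median of 0.45 (percentile 100) and 8 of 13 above both, among them mt-Nd4 at 0.84 and 0.76 and mt-Nd1 at 0.60 and 0.56. Non-clustered protocadherins had a median of 0.46 (percentile 99.7), 6 of 8 above both: Pcdh11x had 1.68 and 2.16, Pcdh17 1.28 and 1.01, and Pcdh8 2.30 and 0.92. Receptor choice regulators had a median of 0.25 (percentile 97.9), 11 of 18 above both, with Emx2 at 0.76 and 1.23 and Nfib at 0.58 and 0.65, while Nfix had -1.49 and -1.02.

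The other 8 lists in Rad21cKO_OSN lay inside the central 95% of random lists. Transduction genes had a median log2 ratio of 0.13 (percentile 81.0), 7 of 18 above both, with the exchanger gene Slc24a4 at 0.98 and 1.40. Axon guidance genes had a median of -0.06 (percentile 13.9) and went both ways: Ptprd had 2.51 and 2.80, Plxna1 1.29 and 1.21, Kirrel3 -2.81 and -1.45, and Nrp1 -1.75 and -1.73. Activity-dependent genes had -0.18 (percentile 8.23), with S100a5 at -1.11 and -2.15 and Fosb at -0.95 and -0.77. Stress genes had 0.11 (percentile 74.4), with Hspa8 at 0.47 and 0.47 and Btg2 at -1.02 and -2.76. The unfolded protein response had 0.19 (percentile 90.5), with Chac1 at 1.74 and 0.73 and Dnajb9 at -0.85 and -0.83. Interferon genes had 0.15 (percentile 81.2), with Bst2 at 1.11 and 2.28 and B2m at -1.04 and -0.81. The p53 list had 0.15 (percentile 81.0), with Cdkn1a, a cell cycle inhibitor, at -3.54 and -3.11. Markers of mature neurons had a median of -0.01, with Omp at -0.64 and -0.48. Among other cell type markers, neutrophil genes (6.44, or 5.24 with genes at 0 set to 3 UMIs) and Bowman gland genes (3.85, or 3.10) were above random lists, and sustentacular (-1.01), erythrocyte (-2.29), respiratory secretory (-1.73) and immature neuron markers (-0.33) below. Several of these depended on the wild type. Against WT_OSN and WT_total_OE, Bowman gland genes had 7.56 and -1.48, sustentacular 0.85 and -2.89, respiratory secretory 1.15 and -5.19, and erythrocyte -0.01 and -4.33. Neutrophil genes (9.38 and 3.45) and immature neuron markers (-0.23 and -0.38) went the same way against both. The neutrophil and Bowman gland medians rested on 4 and 5 measured genes, and free RNA was not subtracted for marker lists. Bpifb9b, a Bowman gland marker, was at 20263 CPM in nearly empty barcodes of Rad21cKO_OSN against 591 in neurons.

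In WaplcKO_OSN mature neurons, 3 histone H2B genes and Pttg1 were higher than in both wild types, and Hmox1 was lower. Hist1h2bm (chromosome 13, 21722044 to 21722567) was at 21.6 CPM with log2 ratios of 6.87 (6.06 to 7.83) and 8.31 (5.83 to 13.62, from 1 UMI), Hist1h2bb at 18.6 CPM, 63.9-fold above WT_OSN and 7.10 (5.24 to 10.15, from 2 UMIs) above WT_total_OE, and Hist1h2bf at 11.5 CPM, at least 250-fold above WT_OSN and 5.40 above WT_total_OE. Pttg1, which encodes securin, the inhibitor of the protease that cleaves cohesin (chromosome 11, 43420250 to 43426251), was at 70.8 CPM against 2.73 and 2.31 (4.69 and 4.94). It was not particular to this library, since Rad21cKO_OSN had it at 51.1 CPM. Hmox1, the haem-degrading enzyme, was at 7.50 CPM against 73.5 and 33.5 (-3.29 and -2.16). Other H2B genes differed from these, with Hist2h2bb at -1.73 and Hist2h2be at 0.38 by the smaller ratio. Histone genes of this family are near-identical copies, so how UMIs were divided among them is uncertain.

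The other genes named in WaplcKO_OSN were as follows. Lama3 was at 17.0 CPM (7.31, with 7.97 (5.49 to 13.28) against 1 UMI), and Gm6999 at 8.46 CPM (4.86 and 4.15). Bpifb9b was at 32.8 CPM (10.06 (8.20 to 13.11) and 7.91 (6.06 to 10.96), from 2 UMIs in each wild type) and Bpifb9a at 8.23 CPM (8.07 (6.20 to 11.12), and at least 40.4-fold), with 5997 and 1597 CPM in nearly empty barcodes. Tmem204, a membrane protein of cell junctions, was at 8.21 CPM (9.06 (6.57 to 14.37) against 1 UMI, and at least 40.3-fold), and Brinp1 at 6.82 CPM (4.80, with 5.65 (3.79 to 8.70) against 2 UMIs). AA388235 was at least 130-fold and 29.4-fold higher and the immunoglobulin gene Igkv2-109 at least 88.6-fold and 20.04-fold. Lower genes were Gm10260 (-9.45 and -9.81), Miat (-6.09 and -6.44), Ccdc141 (-4.49 and -7.17), H2-DMb1 (-5.16 and -3.61), Nexn (-3.06 and -4.33), Gm47851 (-3.00 and -2.90), Gm13757 (-2.17 and -3.52), the deoxyribose-phosphate aldolase gene Dera (-2.64 and -2.45) and Aebp1 (-2.61 and -2.47). Gm21887, on chromosome X, had -4.17 and -4.24 in this library, the one with Xist at 0 CPM and with Ddx3y at 19.0. BC023719 had no UMI, at least 671-fold and 278-fold lower. Among genes well expressed in both wild types, the dorsal zone gene Nqo1 was at 1209 CPM against 384 and 272 (1.65 and 2.15), Mfge8 at 294 against 64.4 and 84.9 (2.19 and 1.79), and the matrix protein Matn2 had 2.09 and 2.45. With 100 UMIs required in both wild types, a rule chosen after the data had been seen, 12 of the 24 named genes were still named, and with WT_total_OE alone 10 were.

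Gene lists in WaplcKO_OSN differed from random lists for 6 of 13. Immature neuron genes were higher, with a median log2 ratio of 0.60 (percentile 100), 10 of 16 above both wild types and none below; Dpysl3 had 3.49 and 1.34, Gap43 1.42 and 0.72, Dcx 1.04 and 0.80, and Stmn4 0.63 and 0.75. Immature neuron markers, a list that shares members with it, had a median of 0.49 (percentile 99.9). Non-clustered protocadherins had 0.33 (percentile 99.8), with Pcdh19 at 0.75 and 0.99, Pcdh8 at 2.13 and 0.74 and Pcdh1 at 0.67 and 0.65. Axon guidance genes had 0.17 (percentile 98.0), 14 of 27 above both, with Ptprd at 1.01 and 1.30, while Cntnap2 was at 0.48 CPM against 1.47 and 1.90 and Epha7 had log2 ratios of -0.65 and -1.48. Transduction genes had a median of -0.18 (percentile 0.07), from -0.38 against WT_OSN but -0.005 against WT_total_OE. Of 18, 9 were below both, among them the phosphodiesterase gene Pde1c at -0.99 and -0.67. Ribosomal protein genes had -0.12 (percentile 0), 41 of 96 below both, with Rps18 at 2.45 and 2.72. Activity-dependent genes had -0.17 (percentile 1.66), with Lrrc3b at -0.94 and -1.37 and Kirrel2 at -0.44 and -1.56. Against WT_OSN alone the median of the activity-dependent list turned to 0.40 and that of ribosomal protein genes to 0.01.

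The other 7 lists in WaplcKO_OSN lay inside the central 95% of random lists. Receptor choice regulators had a median log2 ratio of -0.03 (percentile 22.9), with Nfix at -1.16 and -0.69 and the lamin B receptor gene Lbr at -1.18 and -0.71. Stress genes had 0.07 (percentile 62.1), with Ier2 at -1.20 and -1.30, and the unfolded protein response 0.03 (percentile 57.3), with Dnajb9 at -0.99 and -0.97. Interferon genes had -0.06 (percentile 13.6), with Ifi27 at -2.35 and -0.91. The p53 list had 0.23 (percentile 93.4; 0.03 with genes at 0 set to 3 UMIs), with Cdkn1a at 0.68 and 1.11. Mitochondrially encoded genes had -0.03 (percentile 20.9), with mt-Nd5 at -0.30 and -0.48. Markers of mature neurons had -0.12, inside random lists, with Omp at -0.43 and -0.27. Sustentacular (-1.49), glial (-3.04), macrophage (-3.24), neutrophil (-2.33) and erythrocyte markers (-8.64) were below random lists. With genes at 0 set to 3 UMIs, the macrophage median was -1.36, the neutrophil median -0.94 and the erythrocyte median -6.44. Against WT_OSN and WT_total_OE, sustentacular markers had 0.38 and -3.21 and neutrophil markers 0.56 and -5.22, opposite ways. Glial (-0.88 and -5.61), macrophage (-1.41 and -5.08) and erythrocyte markers (-6.28 and -11.23) were lower against both.

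Wild-type whole epithelium gave the levels of these genes along the neuronal lineage, from 228 immediate precursors through 521 immature neurons to 1750.0 mature neurons. Pcdhac2 was at 29.6 CPM (22.5 to 38.1) in precursors, 47.4 (41.7 to 53.8) in immature and 11.0 (9.37 to 12.8) in mature neurons. Pcdhb1 was at 14.5, 24.1 and 120 CPM in the same order. Alternate alpha isoforms were at 30.6 CPM (23.4 to 39.3), 91.2 (83.1 to 99.8) and 93.8 (88.9 to 98.9), beta 2 to 22 at 56.1, 109 and 94.6, gamma A and B at 39.1, 63.5 and 45.4, and gamma C at 43.1, 12.2 and 5.43. Wapl was at 160.4 CPM in precursors, 76.7 in immature and 58.6 in mature neurons, Rad21 at 131, 103 and 143, and Smc3 at 224, 185 and 103. Omp, the marker of maturity, was at 288, 565 and 4938 CPM, and Gap43 at 445, 2655 and 83.0. Outside the lineage, ensheathing glia had gamma C at 105 CPM and gamma A and B at 119 but alternate alpha at 5.01, and sustentacular cells had Pcdhac2 at 24.3 CPM.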

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

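The tests of immature neurons behind the Pcdhac2 pattern and of sex behind the genes shared by the knockouts were chosen after the results they measure were seen, and the splits of neurons by Nqo1 and by cluster were added after the data had been seen.

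Several results stood on opposite sides of wild type in the 2 knockout libraries, by the smaller of the log2 ratios against WT_OSN and WT_total_OE. The difference between the knockouts was not tested, since each had 1 library. Alternate alpha isoforms had -2.18 in Rad21cKO_OSN and 0.50 in WaplcKO_OSN, and beta isoforms 2 to 22 -2.75 and 0.45. All clustered isoforms together had -0.39 and 0.19. Among cohesin genes, Stag1 had 0.80 and -1.02, Ctcf 0.16 and -0.24, and Wapl itself 0.20 and -1.49. A further signal lay outside the neurons: Bpifb9b was at 20263 CPM in barcodes of 1 to 50 UMIs of Rad21cKO_OSN, against 1.26 in WT_OSN, 3.26 in WT_total_OE and 5997 in WaplcKO_OSN.

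In Rad21cKO_OSN mature neurons, Pcdhac2 was higher and alternate alpha isoforms were lower than in both wild types, and wild-type immature neurons have more Pcdhac2 than mature ones. A larger share of immature neurons is argued against, because the immature neuron list was itself lower, with a median of -0.29 against the nearer wild type, and free RNA is argued against as the whole cause, because Pcdhac2 was still at 1.86 once it was subtracted and was at 36.3 CPM in nearly empty barcodes, below the 44.2 in neurons. Loss of Rad21 stays open: neurons with a Rad21 UMI had alternate alpha isoforms at 0.25 (-0.06 to 0.56) over those without, against -0.11 and -0.13 for the same split in the wild types. The other groups did not follow in that split, with Pcdhac2 at 0.12 (-0.11 to 0.33), beta 2 to 22 at -0.037 and gamma A and B at 0.068, and the 53 neurons of clusters 1, 5 and 7, low in Rad21, had alternate alpha at 0.17 and 0.30. A floxed allele can still give UMIs, so a Rad21 UMI may not mark a neuron with intact Rad21, and the split does not decide.

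Some genes were at least 4-fold apart from both wild types in the same direction in both knockouts, 22 higher and 9 lower, where independent draws would give 0.241 and 0.132. Simulated knockouts without any difference, set against the same controls, shared 0 in each direction, which covers counting error but not a trait common to the 2 wild-type libraries. Sex as a shared cause is argued against: Xist was at 376 CPM in Rad21cKO_OSN and 237 and 241 in the wild types, but at 0 in WaplcKO_OSN, where Ddx3y was at 19.0. A difference of the animals outside the reach of Omp-cre, such as strain, stays open. In cells outside the neuronal lineage, the genes expressed there had a median log2 ratio against WT_total_OE, signed by the direction in neurons. It was 1.40 in WaplcKO_OSN and 2.07 in Rad21cKO_OSN. Of these genes, 9 of 18 in WaplcKO_OSN and 10 of 15 in Rad21cKO_OSN reached 1 log2 unit, and 3 and 2 went the opposite way. Those cells differ in kind, with sustentacular cells making up 905 of 1613 in WT_total_OE, 430 of 620 in WaplcKO_OSN and 20 of 362 in Rad21cKO_OSN, so part of these ratios could reflect the mix of cell types, which was not tested. Free RNA was not subtracted from those cells, and some of these genes differed the same way in nearly empty barcodes. Bpifb9b was there at 20263 CPM in Rad21cKO_OSN and 5997 in WaplcKO_OSN, against 1.26 in WT_OSN and 3.26 in WT_total_OE. Gm10260 was there at 0 and 0.45 CPM, against 213 and 409. For the genes as a set, the test therefore cannot tell a difference of those cells from free RNA or from their mix. For Gm10260, those cells had 788 CPM in WT_total_OE, above the 409 in its nearly empty barcodes, so free RNA cannot account for that level. In Rad21cKO_OSN and WaplcKO_OSN those cells had it at 0.26 and 0.40 CPM, and mature neurons at 0.07 and 0.36. Counts of this predicted gene are uncertain.

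In WaplcKO_OSN, 2 beta UMIs of a neuron were of the same isoform in 28.7% (26.5 to 31.0) of neurons. The share was 47.3% (44.8 to 49.7) in WT_OSN and 35.6% (30.5 to 41.0) in WT_total_OE. The interval of WaplcKO_OSN thus overlapped that of WT_total_OE, and the wild types lay apart from each other. Among the neurons of clusters 1, 5 and 7, where most of WaplcKO_OSN lies, the gap was smaller. The shares were 29.0% (26.8 to 31.4) against 39.6% (31.2 to 48.4) and 32.0% (23.0 to 42.1), and the interval then overlapped that of WT_OSN as well. A difference in the kind of neuron stays open. Immature neurons are argued against as the whole cause: among neurons with a maturity marker and no Gap43 or Gng8 UMI, the share was 28.1% (25.1 to 31.2) against 47.6% and 41.1% (34.8 to 47.7). Doublets and dorsal neurons are left undecided. In neurons with at most 1 receptor the shares were 30.7% (28.4 to 33.2) against 49.4% and 35.4% (29.8 to 41.3). In neurons without a Nqo1 UMI they were 29.5% (26.7 to 32.5) against 49.2% and 36.1% (30.2 to 42.3). Both sets were close to the shares of all neurons. The tests could not exclude either explanation, because they required intervals apart from both wild types, and those of WaplcKO_OSN and WT_total_OE overlapped before any filter. A broader choice of beta isoforms after loss of Wapl was not tested apart from these or from the difference in sex, and stays open.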

How the results depend on the processing

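The tests that split neurons by Nqo1, that used cluster 6 or clusters 1, 5 and 7, and that required 100 UMIs in both wild types were chosen after the data had been seen, as was the measure used here. That measure is the smaller in size of the log2 ratios against the 2 wild types, at 0 where they point opposite ways. No paired analysis was possible because each group had 1 library, and no test was run under any setting. The cause was not tested for any value below, except that against a single wild type the value is by construction the ratio to that library.

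Of the main results under the alternatives, 257 stayed within their counting interval (or within 1.5 times for counts), 71 moved beyond it and 2 turned direction; for single genes and lists these numbers were 470.0, 166 and 2. In Rad21cKO_OSN, alternate alpha isoforms ranged from -2.69 to -2.05, beta 2 to 22 from -2.96 to -2.60, Pcdhac2 from 1.51 to 2.10, gamma A and B from -2.55 to -1.70 and gamma C from -1.46 to -0.78. In WaplcKO_OSN, alternate alpha ranged from 0.23 to 0.51, beta 2 to 22 from 0.22 to 0.51 and gamma C from -2.07 to -1.32. Cluster 6 entered these ranges for Rad21cKO_OSN only, and clusters 1, 5 and 7 for WaplcKO_OSN only. The few Rad21cKO_OSN neurons of clusters 1, 5 and 7, given elsewhere, lay outside the ranges of alternate alpha, Pcdhac2 and beta 2 to 22, nearer wild type. Rad21 in Rad21cKO_OSN ranged from -3.91 to -3.56 and Wapl in WaplcKO_OSN from -1.89 to -1.40. The number of lists outside the central 95% ranged from 4 to 7 and from 5 to 6. At most 5% mitochondrial UMIs, no filter on low counts and isoforms with at least 20 UMIs alone moved no main result.

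With each library clustered by itself, Rad21 was -3.56 in Rad21cKO_OSN, alternate alpha -2.33, Pcdhac2 1.51, Pcdhb1 0.10, beta 2 to 22 -2.96, gamma A and B -2.01 and the share with a leading receptor 94.2%. In WaplcKO_OSN, Pcdhac2 turned to -0.023 and olfactory receptors were -0.14. Pcdhac2 in immature over mature WT_total_OE neurons was 1.47. In neurons with a maturity marker and no Gap43 or Gng8 UMI, Rad21 was -3.85 and Pcdhac2 2.10 in Rad21cKO_OSN. In WaplcKO_OSN, Pcdhac1 was 0, Pcdhb1 0.012, gamma C -2.07, receptors -0.24, the thinned share with an isoform 59.1% and the share with a leading receptor 90.8%.

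Against WT_OSN alone, Rad21 was -3.91, gamma A and B -2.18 and receptors -0.18 in Rad21cKO_OSN. In WaplcKO_OSN, Wapl was -1.89, Pcdhb1 -0.10 and receptors -0.33, 11 of 24 named genes were shared, and the medians of the activity-dependent and ribosomal protein lists turned to 0.40 and 0.0050. Against WT_total_OE alone, Pcdhb1 was 0.65 and receptors 0.033 in Rad21cKO_OSN, with 14 named genes shared. In WaplcKO_OSN, Pcdhac1 was 0.90, Pcdhb1 and beta 2 to 22 0.51 each and gamma A and B 0.36, with 10 named genes shared.

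With cells thinned to 3000 UMIs, Rad21 was -3.56, alternate alpha -2.30, beta 2 to 22 -2.60 and the share with a leading receptor 91.4% in Rad21cKO_OSN, and beta 2 to 22 0.32, receptors -0.15 and that share 89.6% in WaplcKO_OSN; 14 and 9 named genes were shared. With all UMIs, 62.7% of Rad21cKO_OSN and 95.5% of WaplcKO_OSN neurons had an isoform other than Pcdhb1. A minimum of 1000 UMIs gave Pcdhb1 0.093 and a thinned share of 25.9% in Rad21cKO_OSN and receptors -0.11 in WaplcKO_OSN. In WaplcKO_OSN, receptors were -0.10 with doublets kept, -0.15 with TMM factors, -0.14 without receptor, mitochondrial and ribosomal genes in the scale, and -0.14 with free RNA subtracted. TMM factors gave beta 2 to 22 0.36 in WaplcKO_OSN. With free RNA subtracted, at a share that Bpifb9b shows to be too high in the knockouts, 11 of the 24 genes named in Rad21cKO_OSN were shared.

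In neurons with a Nqo1 UMI, alternate alpha was -2.05 and Pcdhb1 0 in Rad21cKO_OSN, and Pcdhb1 0.057 and gamma A and B 0.16 in WaplcKO_OSN; without one, Pcdhb1 was 0.10 in Rad21cKO_OSN. In cluster 6, Rad21cKO_OSN had alternate alpha -2.69, Pcdhac1 -0.77, Pcdhac2 1.57, Pcdhb1 0, beta 2 to 22 -2.89, gamma A and B -2.55 and gamma C -1.46. In clusters 1, 5 and 7, WaplcKO_OSN had alternate alpha 0.23, Pcdhac1 0, beta 2 to 22 0.22, gamma A and B 0.16 and gamma C -2.02, and Pcdhac2 turned to -0.63. With 100 UMIs required in both wild types, 12 named genes were shared in each knockout.

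Shares of cells have no value under TMM factors, under another scale, with free RNA subtracted or against a single wild type. Depth limits the rarer isoforms: WT_total_OE had 14731537 UMIs in mature neurons, so Pcdhac2 rested there on 162 UMIs.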

Other observations

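The tests of position along the beta genes, and the values of the 53 neurons, were chosen after the results were seen.

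Cells outside the mature class gave further values. Immature neurons of WaplcKO_OSN (379 cells) had alternate alpha isoforms at 131 CPM, Pcdhac2 at 33.4, Pcdhb1 at 58.2, beta 2 to 22 at 123 and Wapl at 35.8, and those of WT_total_OE (521 cells) 91.2, 47.4, 24.1, 109 and 76.7. In WT_total_OE, erythrocytes had no UMI of alternate alpha, Pcdhac2, Pcdhb1 or beta isoforms in 114 cells at a median depth of 5722.5 UMIs, while Rad21 was at 553 CPM, Wapl at 343 and Esco2, which acetylates cohesin, at 407. Ensheathing glia had beta 2 to 22 at 88.9 CPM, and horizontal basal cells beta 2 to 22 at 55.6 but alternate alpha at 2.92. The 53 Rad21cKO_OSN neurons in clusters 1, 5 and 7, with Rad21 at -2.97 and -2.62, had Pcdhac2 at -0.10 and 0.20 from 15 UMIs and beta 2 to 22 at -0.67 and -0.57 from 47 UMIs.

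Among the 31 genes apart from wild type the same way in both knockouts, Pttg1 was at 51.1 CPM in Rad21cKO_OSN and 70.8 in WaplcKO_OSN against 2.73 and 2.31, and the class I antigen gene H2-K1 at 25.5 and 22.4 against 0.26 and 2.10. Bpifb9a, Bpifb9b, Lama3, Gm6999, AA388235, Creb5, Elmo1 and Lcn11 were also higher, and Miat, Nexn, Ccdc141, H2-DMb1, BC023719, Gm10260, Gm13757, Gm47851 and Slc7a8 lower. From sustentacular markers alone, free RNA was estimated at 16.5% of mature neuron UMIs in WT_OSN, 2.72% in WT_total_OE, 7.97% in Rad21cKO_OSN and 1.20% in WaplcKO_OSN. In the knockouts this is too high for other genes: Bpifb9b, at 591 CPM in neurons and 20263 in nearly empty barcodes of Rad21cKO_OSN and at 32.8 and 5997 in WaplcKO_OSN, allows smaller shares.

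Loss of Wapl may raise beta isoforms by their position, most at the alpha end. For beta isoforms 2 to 22 this hypothesis was not borne out: Spearman's rho of position and ratio was -0.709 against WT_OSN but -0.068 against WT_total_OE, and -0.655 between the wild types themselves. The other groups went apart: rho was -0.422 and -0.465 for gamma A and B isoforms, with 0.276 between the wild types, and -0.483 and 0.189 for alternate alpha isoforms, with -0.392.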
